A study of Arabidopsis thaliana with 3 samples.

How the data were processed

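Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map where AtHB25 sits on the genome of Arabidopsis thaliana seeds. AtHB25 is a zinc finger homeodomain (ZF-HD) transcription factor. Per the labels' protocols, plants of the Col-0 ecotype lacking HB22 and HB25 carried an HA-tagged AtHB25 gene under the UBQ10 promoter, and about 5 g of seed-enriched material was taken from siliques 7 to 14 days after pollination. The samples formed 2 groups, with 2 ChIP libraries made with an antibody against HA and 1 library made without antibody. Reads were single and 50 bp long. The labels do not say whether the 2 ChIP libraries came from separate plants.

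Per the submitters' processing notes, cutadapt, BWA, SAMtools, Picard, MACS2 and HOMER were used with the TAIR10 genome, and the settings of the aligner are not given in the sources used here. Per the file headers, MACS2 version 2.1.1.20160309 called peaks on both ChIP libraries pooled against the library without antibody, at a q-value limit of 0.05 and an effective genome size of 111.8 Mb. The header gives 6428825 ChIP reads, of which 6103330 remained after duplicate filtering, and 2946232 control reads, of which 2866920 remained. Depth per ChIP library was not given separately. The fragment length estimate was 50 bp, equal to the read length, and the header lists 124 bp and longer values as alternatives. Because both ChIP libraries were pooled before calling, no peak has a value per replicate, no spread between replicates can be given, and no test across samples was made.

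For each peak the authors deposited the pileup at the summit (a coverage signal), the fold enrichment over control (a linear ratio), and −log10 of the p-value and of the q-value. These values are the authors' own and are used here only to describe, rank or filter peaks within their list. The deposited pileup is scaled to the smaller control library. Divided by the ratio of filtered read numbers, 0.470, it gave whole reads within 0.03 for all 216 peaks, so the read number at a summit could be recovered. A genome-wide mean of 1.28 scaled reads follows from the control depth, and the fold enrichment of 115 of the 146 corrected regions equals the pileup plus 1 over this mean plus 1, within 0.01 of a scaled read. For those regions the local control added nothing beyond the genome mean, and the fold rises with the ChIP pileup alone. Exact Poisson intervals (95%) for reads at a summit and Wilson intervals (95%) for shares cover counting error only.

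The authors also deposited a corrected table of 146 regions, in which some neighbouring peaks are joined, a table of 331 genes lying within 3 kb of them (PlantGenIE, per the file headers), in which each gene stands once, a table of distances from regions to transcription starts (PAVIS, per the file headers), and a table of ATHB25 motif matches within 200 bp windows around region centres. The gene ontology table, the table of genes of 2 of its terms and the table of known motifs are the authors' results, made with agriGO and HOMER per the file headers, with the motif background drawn from the genome. In the motif table the deposited target and background shares are fractions, printed here as percentages, and its p-values come from the authors with no adjustment shown. Motif matches on both strands of the same 6 bases were counted as 1 site. Match numbers given for a region are the authors' and count each strand, so 1 TAATTA site can give 2 matches.

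Gene symbols and gene order came from the RefSeq annotation of assembly TAIR10.1, whose name differs from the build of the files, so none of its coordinates were used. Of the 331 genes, 325 matched its 27444 protein-coding genes on the 5 nuclear chromosomes and 6 did not. The groups, the gene lists, the tests and most alternatives were chosen before the data were examined. The 7 lists cover cutin, suberin and wax (lipid barriers are a subject of the series' title), phenylpropanoids and lignin, flavonoids and seed coat pigment, gibberellin, seed maturation, the ZF-HD and MIF family, and highly transcribed genes outside the seed programme. Each was tested with Fisher's exact test (two-sided) among the genes of the 3 kb table against the protein-coding genes, with Benjamini-Hochberg adjustment over the 7 lists. Median fold enrichment of regions with and without TAATTA was compared with a two-sided permutation test of 100000 resamples.

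Genes are named by a rule. It takes at most 2 genes for each of the 15 regions with the highest fold enrichment, beginning with the gene of the distance table and then in the order of the 3 kb table, which gives no distances. It also takes every list member in the 3 kb table, the 10 genes of the 2 ontology terms with the highest fold, and HB25, HB22 and UBQ10. Genes named outside it are marked as such, apart from AT2G45960, AT3G10572 and AT3G62400, which are given only as the nearest gene to the region of a list gene. The nearest gene of a region means the gene that the distance table assigns to it, and the start of another gene can lie nearer.

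The planned tests of promoter and motif shares against random placements and matched control windows need a genome sequence and strands of that build, which were not used here. Those shares are therefore given with intervals and without a test against chance. Rotation tests moved all sites of a region together around its window, or moved the peak genes along the gene order of each chromosome, 10000 times. On simulated data, the rotation of sites gave p below 0.05 in 4 of 100 runs with random sites. It did so in 100 of 100 with sites drawn around the centre with a standard deviation of 42 bp. Weaker clustering, such as that of the data, was not simulated. Fisher's exact test gave p below 0.05 in 2 of 100 runs with random lists of 56 genes, and so did the rotation of gene order. With 4 peak genes planted, both did so in 100 of 100. The planting set that outcome, so it does not show how well either test detects an effect. The median test gave 5 of 100 with no effect and 97 of 100 with fold raised by 0.8. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.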

Results

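The experiment asked where AtHB25, tagged and expressed from the UBQ10 promoter, binds in the genome of seed-enriched material. Binding of AtHB25 expressed from its own promoter was not mapped. The pooled ChIP libraries held 6103330 filtered reads and the library without antibody 2866920, a ratio of 2.13. MACS2 listed 216 peaks, and the corrected table held 146 regions on the nuclear chromosomes, 37 on chromosome 1, 17 on chromosome 2, 27 on chromosome 3, 22 on chromosome 4 and 43 on chromosome 5. Fold enrichment over the control ran from 3.77 to 10.1 with a median of 5.54. Regions were 50 to 962 bp wide, with a median of 92 bp. The summits held 19 to 47 ChIP reads, with a median of 25, where a genome-wide mean of 2.73 reads follows from the control depth. The exact Poisson intervals were 11.4 to 29.7 for 19 reads, 16.2 to 36.9 for 25 and 34.5 to 62.5 for 47, so folds of neighbouring ranks lie within counting error of each other. With 2 pooled ChIP libraries and 1 control library there was no replicate check of any region. No library was made with the HA antibody from plants without the tag. Signal that the antibody gives without tagged AtHB25 therefore cannot be told apart from AtHB25 binding.

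The strongest region lay at the promoter of ICE1 (AT3G26744), a basic helix-loop-helix factor of cold response and stomatal development. It spanned chromosome 3, positions 9835133 to 9835456 (TAIR10), 47 bp upstream of the transcription start. Its fold enrichment was 10.1 from 47 reads, and it held 4 ATHB25 motif matches at 2 sites. Next came a region on chromosome 5 (26078179 to 26078504) with a fold of 9.29, 87 bp upstream of AT5G65240, a leucine-rich repeat protein kinase, with AT5G65250 also within 3 kb. A region on chromosome 5 (26822114 to 26822395) reached 8.47, 224 bp upstream of IRX14-L (AT5G67230), which with its neighbour IRX15-L (AT5G67210) belongs to families that build xylan in the secondary cell wall. A region on chromosome 1 (29734329 to 29734456) reached 7.64 and held 9 motif matches at 5 sites. It lay 781 bp upstream of AT1G79030, a DnaJ-domain chaperone gene, and near PSBR (AT1G79040), a subunit of photosystem II.

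Of the 15 regions highest in fold, 11 others ranged from 7.02 to 7.44, which corresponds to 32 to 35 reads. KCS20 (AT5G43760), a ketoacyl-CoA synthase that lengthens fatty acids for wax and suberin, lay within 3 kb of a region on chromosome 5 (17591511 to 17591761). That region had a fold of 7.44 and 8 motif matches at 5 sites. Its nearest gene, however, was APS4 (AT5G43780), with a start at 101 bp. The mitochondrial acyl carrier protein gene mtACP3 (AT5G47630) lay near a region of fold 7.23 on chromosome 5 (19308524 to 19308822) that was 554 bp upstream of NF-YB2 (AT5G47640), a subunit of the CCAAT-binding nuclear factor Y. WES1 (AT4G27260), a GH3 enzyme that conjugates auxin to amino acids, had a region of fold 7.02 centred 609 bp upstream of its start on chromosome 4 (13652520 to 13653481). This region joins 2 separate peaks, and its centre lies between them. The fold of 7.02 belongs to the peak nearer the start (13653317 to 13653481), and the other peak (13652520 to 13652620) had 4.55.

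Regions of fold 7.02 to 7.44 also stood directly at the starts of several less studied genes. The region at J11 (AT4G36040), a DnaJ-domain chaperone, was centred 157 bp upstream with a fold of 7.42 and had AT4G36050 as its neighbour. The region at TTL4 (AT3G58620), a tetratricopeptide-repeat thioredoxin-like gene, was 114 bp upstream with a fold of 7.23 and held no ATHB25 match. RSH3 (AT1G54130), a RelA/SpoT homologue, had a region 140 bp upstream with a fold of 7.02 and 4 matches at 3 sites. Regions in the 5′ untranslated region were found at AT3G20350 (fold 7.23, neighbour AT3G20340), at the RING finger gene AT1G12760 (fold 7.02, neighbour RBL6, AT1G12750), and at AT1G17620, a late embryogenesis abundant glycoprotein gene (fold 7.02, neighbour AT1G17615). The region of AT3G05625 (fold 7.02) lay 75 bp upstream and had AT3G05620, a pectin methylesterase inhibitor family gene, within 3 kb. AT5G03370, an acylphosphatase family gene, had its region of fold 7.44 farther away, 1767 bp upstream.

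**Figure D1:**
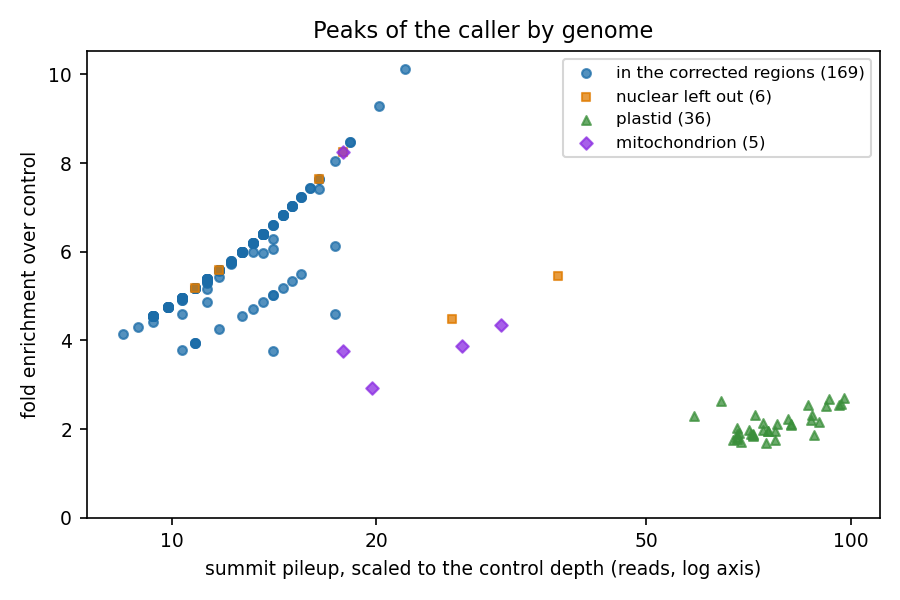
Each point is 1 of the 216 peaks of the caller, placed by its summit pileup in reads scaled to the control depth (log axis) and its fold enrichment over the control. The 169 peaks inside the corrected regions reach folds of 3.77 to 10.1 at pileups of 8.46 to 22.1, while the 36 plastid peaks have pileups of 58.7 to 97.7 and folds of at most 2.70.

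All 146 corrected regions overlapped a peak of the caller by at least 1 bp, and 123 had identical start and end. Of the 216 peaks, 169 lay in these regions and 47 were left out. Of the regions, 125 held 1 peak, 19 joined 2 peaks and 2 joined 3. All 21 joined regions carry the fold of their right-most peak, which in 9 of them was below the strongest peak inside. A region on chromosome 5 (4633699 to 4634200), 236 bp upstream of the CCT motif gene AT5G14370, is listed at 3.93 and holds a peak of 8.47. This gene was chosen after its values were seen.

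The called regions sat close upstream of genes. Of the 142 regions with a location in the distance table, 111 lay upstream of the nearest gene (78.2%, Wilson interval 70.7 to 84.2), 11 in a 5′ untranslated region, 11 downstream, and 3 each in a 3′ untranslated region, an exon and an intron. The median position was -121 bp from the transcription start, with quartiles of -263 and -32.8 bp. Within 200 bp upstream lay 64 regions (45.1%, 37.1 to 53.3) and within 1 kb upstream 95 (66.9%, 58.8 to 74.1). Within 3 kb of the start of the nearest gene, in either direction, lay 136 (95.8%, 91.1 to 98.0). A comparison with randomly placed regions was not run.

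**Figure D2:**
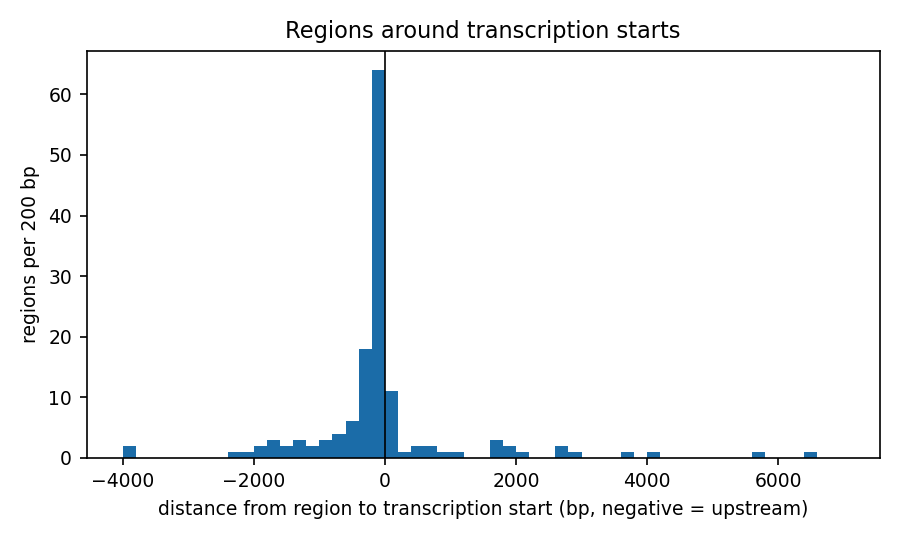
Histogram of the distance from each of 142 regions to the transcription start of its nearest gene in bp (negative is upstream), in bins of 200 bp. The bin just upstream of the start holds 64 regions, more than any other bin, with a median position of -121 bp.

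Most regions held a match to the motif of AtHB25. An ATHB25 motif match stood within the 200 bp window of 121 of the 146 regions (82.9%, Wilson interval 75.9 to 88.1), and 71 regions held the palindromic core TAATTA (48.6%, 40.7 to 56.7). Another 50 regions (34.2%) had matches without TAATTA, in which the core read TGATTA or TAATCA. Among the 259 sites, 115 were TAATTA, 74 TGATTA and 70 TAATCA. TAATCA is TGATTA read on the opposite strand, so these 2 counts are of the same core. More than 1 TAATTA site stood in 33 regions (22.6%), among them the regions of ICE1 with 2, of KCS20 with 3, and of PSBR with 4. The regions at TTL4 and PIF3 held no match.

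In the authors' deposited table of known motifs, the 5 ZF-HD motifs came first, each well above its background share. ATHB34 stood in 74.8% of the peak sequences and 28.4% of the background (p = 1e-30), and ATHB25 itself in 83.0% against 37.6% (p = 1e-28) in the authors' deposited table. In the authors' deposited table ATHB24 reached 72.1% against 27.0% (p = 1e-29), ATHB23 76.9% against 31.4% (p = 1e-28) and ATHB33 79.6% against 38.3% (p = 1e-23). The motif of SPCH, a helix-loop-helix factor that starts the stomatal lineage, followed with 29.9% against 11.1% (p = 1e-09) in the authors' deposited table. Of the 29 motifs at p = 1e-05 or below in the authors' deposited table, 13 were of the bZIP family. ABF2 reached 12.9% against 3.01% (p = 1e-06) and bZIP53 15.6% against 4.67% (p = 1e-06) in the authors' deposited table. ABI5 reached 14.3% against 4.25% (p = 1e-05) in the authors' deposited table. ABF2, bZIP53 and ABI5 are factors of abscisic acid response and seed maturation. The 13 also held HY5, with the highest share among them (27.9% against 12.6%), GBF3, GBF5, GBF6, bZIP16, bZIP28 and bZIP68. The listing alone therefore does not single out seed factors. Whether the ZF-HD, SPCH and bZIP shares exceed those of promoters was not tested, because the background was drawn from the genome. The authors' deposited table counts 147 sequences and 122 with the ATHB25 motif, 1 more in each case than the 146 regions and the 121 of the match table.

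**Figure D3:**
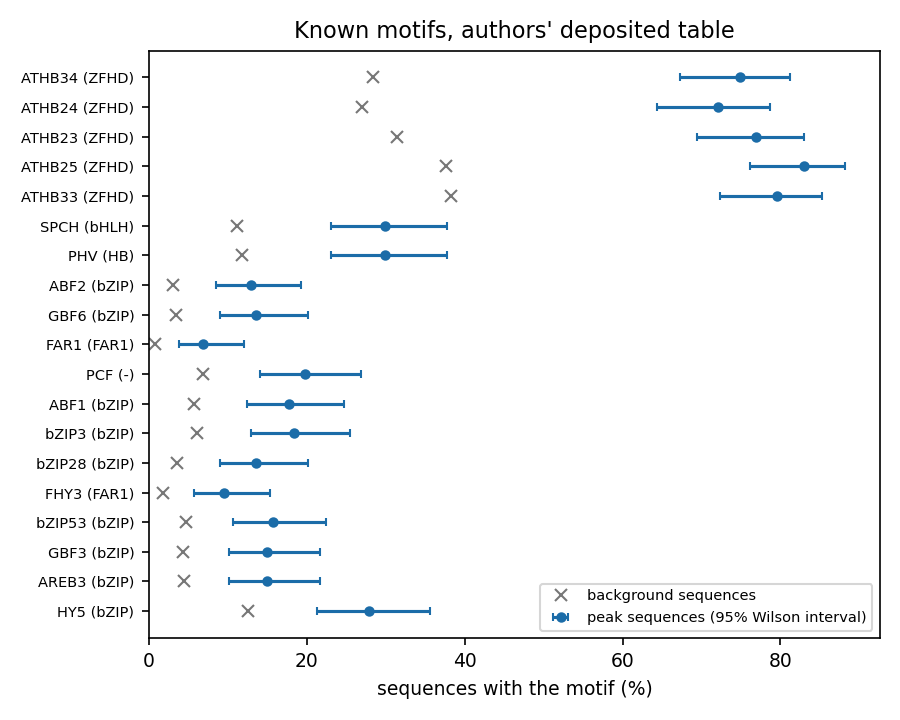
Share of sequences with each known motif in percent, for motifs at p = 1e-06 or below in the authors' deposited table, with peak sequences as points (95% Wilson intervals) and background sequences as crosses. The 5 ZF-HD motifs reach 72.1% to 83.0% of the peak sequences against 27.0% to 38.3% of the background.

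Regions with the core were not distinguishably stronger. The median fold was 5.58 in the 71 regions with TAATTA (quartiles 4.97 and 6.41) and 5.38 in the 75 without (4.97 and 6.20), a difference of 0.206 (permutation test, two-sided, p = 0.708). Regions are not independent replicates, and this test compares regions within 1 list.

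Genes of the cutin, suberin and wax list, the apoplastic lipid barriers of seed coat and epidermis, were the fixed list found near AtHB25 regions more often than other genes. Of its 56 genes, 4 were in the 3 kb table where 0.663 were expected (odds ratio 6.49, Fisher's exact test p = 0.00437, Benjamini-Hochberg adjusted p = 0.0306). They were LACS2, CYP86A8, CYP77A6 and KCS20. LACS2 (AT1G49430), an acyl-CoA synthetase of cutin formation, had a region of fold 6.82 on chromosome 1 (18296653 to 18296713), which lay downstream of the gene and 5640 bp from its start. CYP86A8 (AT2G45970), a fatty acid hydroxylase, was within 3 kb of a region of fold 4.97 on chromosome 2 (18910165 to 18910227). That region held 7 motif matches at 5 sites, and its nearest gene was the aquaporin gene PIP1;2 (AT2G45960), with a start at 99 bp. CYP77A6 (AT3G10570), which hydroxylates cutin monomers, was near a region of fold 4.86 on chromosome 3 (3304146 to 3304219), 86 bp upstream of AT3G10572. With the nearest gene alone, LACS2 was the single member left (odds ratio 3.54, Fisher's exact test, adjusted p = 1). With regions at or above the median fold, LACS2 and KCS20 remained against 0.337 expected, an odds ratio of 6.19 close to that of all regions (Fisher's exact test, adjusted p = 0.313).

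No other fixed list stood apart. The seed maturation list had 1 of 31 genes in the table against 0.367 expected (Fisher's exact test, adjusted p = 1). This was BZIP53 (AT3G62420), a bZIP activator of storage protein genes, near a region of fold 5.17 on chromosome 3 (23089419 to 23089548) that was 158 bp upstream of AT3G62400. The gibberellin list had 0 of 31 (0.367 expected), phenylpropanoid and lignin 0 of 25 (0.296), flavonoid and seed coat pigment 0 of 19 (0.225), the ZF-HD and MIF family 0 of 17 (0.201), and the highly transcribed genes 0 of 19 (0.225), each with an adjusted p of 1. Lists of this size with under 1 gene expected cannot show a depletion. HB25 (AT5G65410), HB22 (AT4G24660) and UBQ10 (AT4G05320), the tagged gene, its mutated relative and the gene that lent the promoter, were not among the 331 genes.

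Genes of auxin response and of post-embryonic development were among the terms in the authors' deposited table of gene ontology. Response to auxin stimulus had 11 of 360 genes (false discovery rate 0.049) and post-embryonic development 16 of 705 (0.049) in the authors' deposited table. Response to chemical stimulus had the lowest rate of the biological processes there (37 of 2085, 0.017). The authors' deposited table also lists carbohydrate metabolic process (19 of 866, 0.049), ubiquitin-protein ligase activity (10 of 324, 0.032) and plasma membrane (26 of 1456, 0.008). The 2 terms together held 25 genes at 24 regions, 2 of them, GRH1 and TCH2, in both. GRH1 and TCH2 fall outside the naming rule and were chosen after their values were seen.

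By fold, the genes of these 2 terms were led by ICE1 (10.1), followed by EMB1586 (AT1G12770), PLDP2 (AT3G05630), a phospholipase D, and WES1, each at 7.02, and LACS2 at 6.82. The regions of EMB1586 and PLDP2 are those given above for AT1G12760 and AT3G05625, which were the nearest genes. MYBR1 (AT5G67300), a MYB factor of abscisic acid response, had a region of fold 6.61 centred 921 bp upstream on chromosome 5 (26853037 to 26853165). TTL3 (AT2G42580), a relative of TTL4, had a region of fold 6.41 centred 161 bp upstream on chromosome 2 (17728438 to 17728671). ERS (AT5G64050), a glutamate tRNA synthetase, reached 6.0 at 16 bp upstream, and TUBG1 (AT3G61650), a gamma-tubulin, 5.79 at 137 bp upstream. PIF3 (AT1G09530), a phytochrome interacting factor, had a region of fold 5.74 on chromosome 1 (3081276 to 3081342) with no entry in the distance table. This order uses the listed folds, and the joined region of SDD1 (AT1G04110), listed at 4.59, holds a peak of 6.07, above ERS, TUBG1 and PIF3. SDD1 was chosen after its values were seen. In 9 of the 16 post-embryonic genes and 7 of the 11 auxin genes, the gene was also the nearest to its region.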

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

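Every test in this part was chosen after its result was seen. Some groups of peaks drew attention because they stood above the control in data that the corrected table leaves out. They were 36 peaks on the plastid genome, 5 on the mitochondrial genome and 6 on the nuclear chromosomes.

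The plastid peaks had folds of 1.69 to 2.70 at pileups of 58.7 to 97.7 scaled reads, over a median implied control of 37.2. The highest plastid fold, 2.70, was below the lowest fold of a peak kept on the nuclear chromosomes, 3.77, while the lowest plastid pileup exceeded the highest pileup of the kept peaks, 22.1. High plastid coverage that lets small ratios pass the caller's threshold is therefore a candidate explanation. The same values cannot decide whether enrichment of the size seen at nuclear regions was present on the plastid genome. At most 3 ChIP reads at the same position were kept, which limits the fold that can be reached over so high a control. Why the ChIP libraries exceed the control there at all stays open, since no biological explanation was tested.

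The 5 mitochondrial peaks ranged from 2.93 to 8.26 in fold. The 6 nuclear peaks ranged from 4.47 to 8.26 in fold, inside the range of the kept regions, but 2 of them lay outside it in other values. A peak on chromosome 2 (3367345 to 3367420) had a pileup of 37.1 scaled reads over an implied control of 6.0, and a peak on chromosome 4 (3222095 to 3222145) had 25.8 over 5.0, where the kept peaks reached at most 22.1 and 3.0. The others include a pair on chromosome 4 (18584837 to 18584886 at 5.58 and 18584986 to 18585035 at 8.26) and a peak on chromosome 2 (3272695 to 3272745) at 7.64. The sequence under these 6 peaks was not examined, and why they were left out was not tested. Their folds alone therefore do not make them AtHB25 sites.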

How the results depend on the processing

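The alternatives that take joined regions at their strongest peak, regions of 1 peak only, the list without joining, any ATHB25 match, and the rotation of gene order were chosen after seeing the data. Fold of 5 or more, the uncorrected list and the list without joining left the number of peaks within 1.5 times of 146, whereas a −log10 q of 10 or more left 2, and the cause was not tested. The share of regions with TAATTA moved from 48.6% to 36.3% within 50 bp of the centre, a narrower window by construction, and to 82.9% with any ATHB25 match, a wider motif by construction. The cutin, suberin and wax list was the 1 list past the threshold. It stayed so under rotation of the gene order (a permutation test, adjusted p = 0.0455). With the nearest gene only, 0 lists passed and 1 member remained, and with regions at or above the median fold 0 lists passed and 2 members remained, also with joined regions at their strongest peak (Fisher's exact test, adjusted p = 0.313 to 1 over these 3, odds ratios 3.54, 6.19 and 5.97 against 6.49). These settings test fewer genes, and the cause was not tested further. The shares near starts and the overlap of the lists moved within their limits, and the comparison of fold with and without TAATTA stayed above p = 0.05 in the permutation test under all 4 alternatives (0.209 to 1). With joined regions at their strongest peak 9 regions changed in fold, none of them at the 36 genes with a region that the naming rule takes, most of which were selected by a high listed fold, so this says little about stability. Not run were leaving out a replicate, because peaks were called on pooled libraries, and random or pericentromere-excluding placements, own gene assignment, protein-coding starts, distances of uncorrected peaks, the 250 bp window (also for fold), the flanked core, flanking windows and unmatched controls, because they need a genome sequence or strands. No paired analysis was possible because peaks were called on pooled libraries.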

Other observations

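Every test in this part was chosen after its result was seen. Beyond the fixed lists, the 3 kb table holds 4 genes of the Aux/IAA family, repressors of auxin response, at 4 separate regions. All 4 are among the 11 genes of response to auxin stimulus given above, so they are not a separate observation from that term. IAA9 (AT5G65670) was the nearest gene to its region on chromosome 5 (26251647 to 26251812, fold 5.38, 8 motif matches at 4 sites), while IAA11, IAA15 and IAA33 had another gene nearer. It also holds 3 of 25 GAUT and GATL genes, which make pectin and related polysaccharides (GAUT6, LGT8 and LGT9), and 3 of 37 cyclin genes (CYCB2;3, CYCD1;1 and CYCP1;1). These genes were named after their values were seen.

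As hypotheses, these families may lie near AtHB25 regions more often than other genes. Rotation of the gene order, a permutation test, gave 0.388 Aux/IAA genes on average against 4 observed (p = 0.0013), 0.281 against 3 for GAUT and GATL (p = 0.0032) and 0.441 against 3 for cyclins (p = 0.0151). These families were also set among 198 families of at least 10 genes, taken from the letters that begin gene symbols and synonyms, except that GAUT with GATL and the cyclin classes were put together by hand and names given for mutant phenotypes, such as EMB, were left out. After adjustment over the 198, Fisher's exact test gave 0.106 for Aux/IAA, 0.309 for GAUT and GATL and 0.376 for cyclins, and 0 families passed 0.05 (6 did without adjustment). Clone names, which group neighbouring genes, were left out after a first scan that held them had been seen, and this choice ended the Aux/IAA call. With them kept, 330 groups gave an adjusted p of 0.0294 for Aux/IAA by Fisher's exact test and 9 groups passed. With letters alone and nothing put together, Fisher's exact test adjusted over 201 families gave 0.107 for Aux/IAA, 0.396 for GATL and 1 for GAUT and for each of the cyclin classes CYCA, CYCB and CYCD, so the GAUT and GATL and the cyclin values above, rotations included, rest on groups put together after they were noticed. Whether Aux/IAA genes lie near regions more often than other genes stays open, because the call depends on which families are scanned and the family was noticed in the same table.

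Motif sites clustered near region centres. The mean distance of the 259 sites from the centre was 42.3 bp, against 48.7 bp after rotation within the window (permutation test, one-sided, p = 0.0010). This argues against sites spread evenly over the windows. The rotation takes base composition as even across the window, and no genome sequence was used. AT content that is itself highest near the centres was therefore not tested. Regions of 1 peak alone gave 41.2 bp against 48.8 bp (223 sites, permutation p = 0.00020), so joined regions did not carry the pattern. TAATTA sites averaged 39.2 bp (permutation p = 0.00070) and sites reading TGATTA or TAATCA 44.8 bp (permutation p = 0.0525), a difference that was not itself tested. Direct binding at these sites may account for the clustering, as a hypothesis found and tested on the same data.

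Joined regions held 23 pairs of neighbouring summits, 95 to 826 bp apart with a median of 158 bp, and 17 lay within 200 bp. The joining itself selects close peaks, so this spacing was not compared with any other. Reads extended by only 50 bp could split a binding site into a pair of summits with the motif between them. In the 12 pairs within 200 bp that came from regions of 2 peaks and held motif sites, 8 of 22 sites lay between the summits, against 13.8 after rotation (permutation p = 0.993 for as many), which argues against it. Sites averaged 27.3 bp from the nearer summit against 35.9 bp after rotation (permutation p = 0.0765), so whether each summit sits on its own site cannot be told apart from chance with 22 sites.

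If joined regions are ranked by their strongest peak, 3 joined regions enter among the 13 highest, followed by 5 regions tied at 7.02. Those that enter are the region at AT5G14370, listed at 3.93 with a peak of 8.47, that of MAP70-1 (AT1G68060), listed at 6.20 with 8.05, and that of the histone gene AT5G10980, listed at 4.97 with 7.64. These genes fall outside the naming rule and were chosen after their values were seen. The summit listed for the region of GAUT6, 208300, lies outside the region (2082993 to 2083201), where the caller lists 2083175.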
